A study of Mus musculus with 9 samples.

How the data were processed

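Total RNA from adult mouse midbrain was hybridised to 9 single-channel exon arrays, 3 from each of 3 genotypes: wild type, Slm1 knockout, and double knockout of Sam68 and Slm1. Slm1 is the gene Khdrbs2 and Sam68 is the gene Khdrbs1; both encode RNA-binding proteins of the STAR family. Genotype and replicate number were taken from the sample labels, which place all animals on a mixed SV129/C57B6 background. The labels do not say that each array came from a separate animal, so p-values measure the spread between these samples, which may in part be technical.

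Per the file headers, the arrays were read with Agilent Feature Extraction 11.5.1.1 under a one-colour (Cy3) protocol on a grid annotated on mouse genome build mm9. The processed spot intensity in the deposited scanner files had been background-subtracted and spatially detrended per spot by that software, per the file headers, and had not been scaled between arrays. The deposited raw intensity columns hold the median brightness of each spot and of its local background without correction. The authors' deposited value table holds log2 values of the same arrays. Its columns had medians between -1.73 and -1.68 and 75th percentiles of 0.00512 to 0.00669, and each correlated with the log2 processed intensity of its own array at r = 1 over probes. Its scale is therefore log2 with the 75th percentile near 0 and no centring per probe, although no source used here states how it was made. The flags used were those that the software set for signal well above background, spot outliers, population outliers, saturation and control spots.

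Each array held 420288 spots, of which 411345 were not controls, covering 235712 probes. No spot was saturated. Between 83.0% and 88.7% of non-control spots per array were well above background, and the 75th percentile of the processed intensity ran from 442.8 to 556.3. The number of arrays limits the precision. Replicates of one genotype correlated at r = 0.984 to 0.996 across probes, and arrays of different genotypes at r = 0.973 to 0.993, so no array was a copy of another.

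The main value was log2 of the processed intensity minus the 75th percentile of its array. Control spots and outlier spots were left out, and spots of one probe were averaged; 466 probes with every spot marked as an outlier on some array were set aside. A probe counted as well above background on an array if more of its spots than not carried that flag, and it was retained if this held on all 3 arrays of at least 1 genotype, which left 197696 probes. Gene symbols came from the probes' RefSeq and other accessions through a table of the GRCm38.p6 assembly, which named 211057 probes under 21817 symbols and left 24655 under the accession or clone name of the array design. The files of the 2 scans carry different versions of the array annotation, which gave different accessions for 8748 probes and different genes for 31; those 31 were left unnamed. Because the assembly differs from that of the array, the table was used only for names, chromosomes and gene neighbourhoods, and no coordinates are given. The probes carry no position within their transcripts in the files used here.

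A gene value was the mean over its retained probes, which gave 31863 gene values, 19980 of them under a symbol. Probe usage was the log2 value of a probe minus the mean of the other retained probes of the gene, computed for 173120 probes in 14433 genes with at least 4 retained probes. A change of one probe therefore shifts the usage of the gene's other probes the opposite way. Both measures were fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3, package data.table, version 1.17.8) over all 9 arrays with genotype as the only term, and each contrast was adjusted by Benjamini-Hochberg with a threshold of 0.05. A moderated F over the 3 genotypes was adjusted in the same way. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Errors given with log2 differences are standard errors from limma with n = 3 arrays per genotype, and all tests were two-sided.

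A probe not well above background on any array of a genotype has only a bound there. Its difference is given as at least N-fold: the mean of the brighter genotype against the mean over the dim arrays of the higher of the lowest signal among probes well above background and the probe's own signal. No fold is given where that bound fell under 1. For probe usage the same bound was taken on the usage scale.

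Genes were named by a rule. It took the 10 largest positive and 10 largest negative differences per contrast among called genes with a symbol whose 3 arrays of one genotype all lay above the 3 of the other, the same for probe usage with at most 1 probe per gene and direction, every called member of the gene lists, and Khdrbs1, Khdrbs2 and Khdrbs3 always. The 32 gene lists covered cell types and regions of the brain, synapses, splicing and polyadenylation factors, metabolism and stress responses, interleukin-1 receptors, and 21 published splicing targets of the STAR proteins. Lists were tested against all other genes with camera in limma at a preset correlation of 0.01, and again with an estimated correlation. The share of known targets with a called probe and the share of calls near the targeted loci were tested with Fisher's exact test. The design, the lists, the naming rule and most alternatives were fixed before the data were examined.

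The files give slide and scan for each array. Slides 1 to 3 each held 1 wild type and 1 double knockout array with the same replicate number and shared a scan. Slide 4 held Slm1 knockout replicates 1 and 2 and slide 5 held replicate 3, in another scan. Wild type and double knockout were therefore also compared with slide as a block and within each slide. No slide or scan held Slm1 knockout arrays with another genotype, so for contrasts with the Slm1 knockout the scan and the genotype cannot be told apart; slide entered those fits as a random block through duplicateCorrelation. Deviations of same-numbered wild type and double knockout arrays from their genotype means correlated at r = 0.40, 0.12 and 0.19 for gene values. For probe usage they correlated at 0.47, 0.19 and 0.23. Same-numbered arrays of the other genotype pairs, which share no slide, ran from -0.08 to 0.28 for gene values and from -0.13 to 0.35 for probe usage. The correlations thus do not establish the pairing, which rests on the shared slides. Other genotype pairs are not paired.

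The procedure was tested on simulated data with 200 changed genes for double knockout against wild type. Over 31863 gene values it recovered 95.5%, 97.0% and 100% of genes changed 1.5-, 2- and 4-fold, with 7.05% of calls false. Over 173120 probes it recovered 16.4%, 59.7% and 90.9% of usage changes of the same sizes, with 5.69% of calls false. A simulated contrast with no change gave 0 calls, and the 1 raised list was called and 0 of the others were. The changed genes all had at least 4 retained probes, and noise was drawn separately for each probe. Recovery of genes with fewer probes, or whose probes vary together, was not tested. In the real data, 47.4% of the gene values called in this contrast rested on 1 probe.

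Alternatives covered background correction by normexp with an offset of 50, quantile normalization, the deposited value table, filters on dim probes, the median over probes, at least 8 probes per gene, the limma function diffSplice, array weights, replicate and slide blocks, fits to 6 arrays, removal of genes near the targeted loci, and leaving out each array. The scanner files used here hold no mean spot brightness, so normexp ran on the median brightness of spot and background. Without probe positions, the planned share of calls in last exons was not computed.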

Results

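Splicing programs of the RNA-binding proteins SAM68 (gene Khdrbs1) and SLM1 (gene Khdrbs2) were screened in the midbrain of adult mice, with the choice between alternative 3′ ends of transcripts as the wider question. Exon arrays, which carry many short probes along each gene, measured 3 wild type, 3 Slm1 knockout and 3 double knockout samples. Between 83.0% and 88.7% of spots per array were well above background and none was saturated. Gene values are means over a gene's probes. Probe usage is the log2 signal of a probe relative to the gene's other probes. A shift in usage can mark a change in the part of the transcript a probe detects, but it also arises when the gene's other probes change. Where a log2 difference below is given with ±, the value after it is its standard error from limma, with n = 3 arrays per genotype. The Slm1 knockout arrays were scanned apart from the others, so in every contrast with them the scan and the genotype cannot be told apart.

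Khdrbs1 signal was lost over part of the gene in the double knockout and kept in the Slm1 knockout. Probe A_56_P011547 was not well above background on any double knockout array and lay at least 75.6-fold lower than in wild type (adjusted p = 3.16e-05), and probe A_56_P010738 was 12.5-fold lower (-3.65 ± 0.11, adjusted p = 4.36e-05). Probes A_52_P574697, A_56_P011552 and A_56_P230276 fell by 2.78, 2.67 and 2.49 on the log2 scale. Probes A_56_P011548, A_56_P011549 and A_56_P011550 rose instead, by 0.80, 2.38 and 1.67. The gene value of Khdrbs1 fell by 1.57 ± 0.06 in the double knockout (adjusted p = 0.000146) and differed by 0.11 in the Slm1 knockout (adjusted p = 0.387). With slide as a block, A_56_P011547 had an adjusted p of 0.113 and no Khdrbs1 probe signal kept its call, while the gene value did (0.0135).

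Khdrbs2 probe A_56_P076294 and Khdrbs1 probe A_56_P011547 were singled out after their values were seen. Of the 9 Khdrbs2 probes, A_56_P076294 fell furthest in both knockouts. Its mean was -2.33 ± 0.10 (SD) in wild type and -7.73 ± 0.37 in the double knockout, where it was not well above background and lay lower by at least 3.52 on the log2 scale (adjusted p = 0.119). In the Slm1 knockout it stood at -7.36 in replicate 1 and -7.58 in replicate 3, both not well above background. In the library labelled Slm1 knockout replicate 2 it stood at -3.14, which is 57.3% of the wild type signal, and both of its spots were well above background. With that library, the Slm1 knockout was not called at this probe (adjusted p = 0.128); without it, both knockouts were called at this probe (adjusted p = 0.000228 and 0.000442 for the double knockout), with no size given since none of their arrays left was well above background. The signal of this probe thus goes against the label of that library, and every direction given below for the Slm1 knockout rests in part on it. Over all 9 arrays the other 8 Khdrbs2 probes were not called either, such as A_56_P076298 at 1.73 in wild type and 1.81 in the double knockout. Probe A_56_P076293 lay lower on every knockout array than on any wild type array (means -0.66, -1.06 and -1.14 in wild type, Slm1 knockout and double knockout). The library labelled Slm1 knockout replicate 2 lay nearest wild type there, at -0.79. Probes A_51_P223724, A_56_P076299 and A_56_P236002 lay higher on every knockout array. Which part of Khdrbs2 is deleted is not given in the sources used here, so the place of A_56_P076294 within it is inferred from these same values, and probes outside the deleted part check nothing. The gene value of Khdrbs3, the remaining SLM family member, lay 0.41 ± 0.09 above wild type in the double knockout without passing the test (adjusted p = 0.128).

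**Figure D1:**
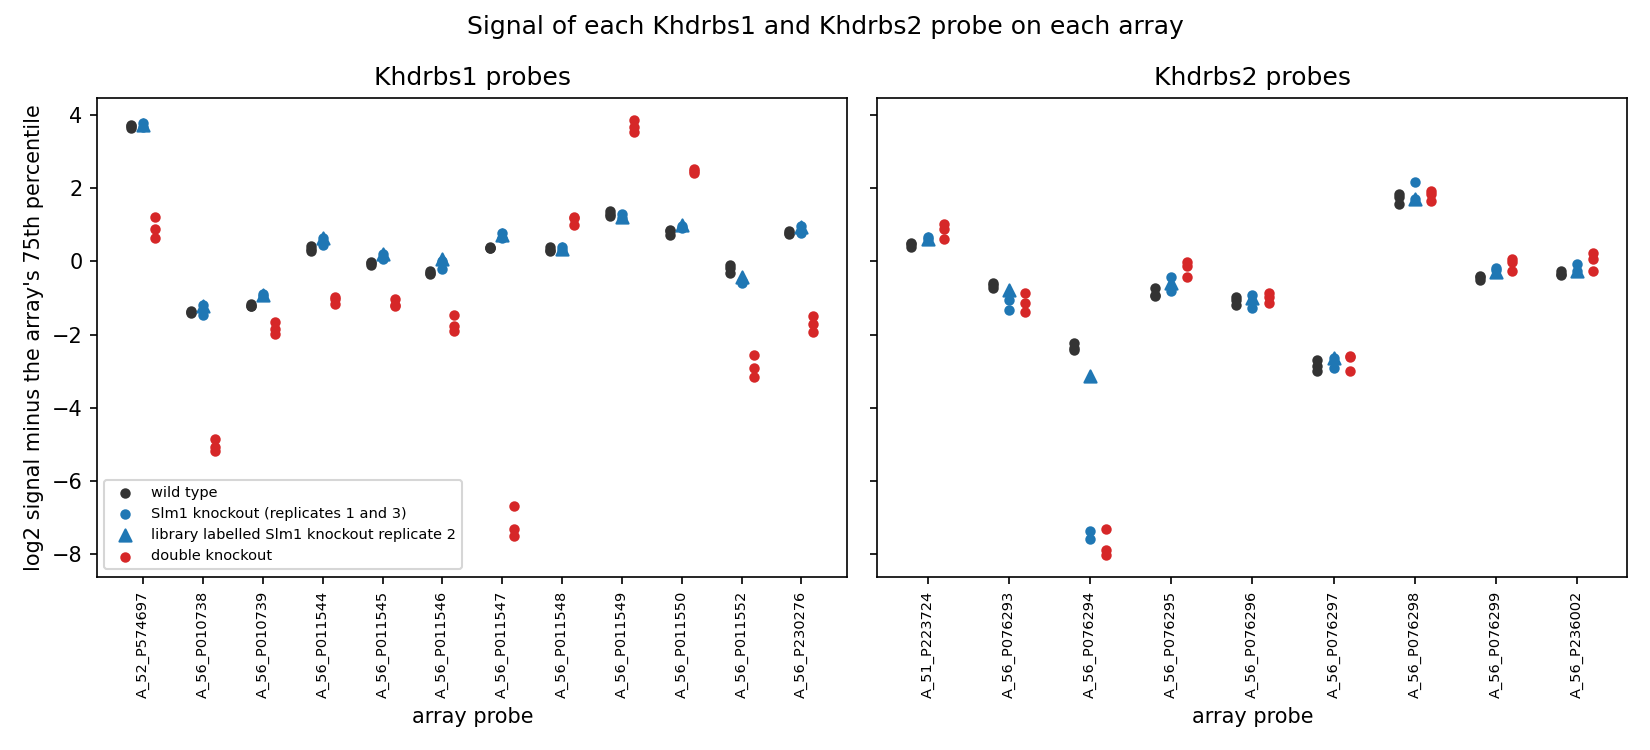
Log2 signal minus the 75th percentile of the array (vertical axis) of each Khdrbs1 and Khdrbs2 probe (horizontal axis) on each of the 9 arrays, 1 point per array and 1 colour per genotype, with a triangle for the library labelled Slm1 knockout replicate 2. Khdrbs1 probe A_56_P011547 drops only in the double knockout, whereas Khdrbs2 probe A_56_P076294 drops in the double knockout and in Slm1 knockout replicates 1 and 3 but stands at -3.14 in the library labelled Slm1 knockout replicate 2.

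The double knockout was compared with wild type to find what changes when both proteins are missing. The genes that fell included the amylase genes Amy2a5 (fell by 2.32 ± 0.09, adjusted p = 0.000146) and Amy1 (fell by 2.29 ± 0.19, adjusted p = 0.00209), which encode starch-digesting enzymes. As close paralogs, the amylase genes can share probe signal, so which of them fell is uncertain. The zinc finger genes Zfp982 and Zfp985 fell by 2.88 and 2.01, and D4Ertd617e was at least 14.3-fold lower. Sycp1, which encodes a component of the synaptonemal complex of meiosis, rose by 2.15 ± 0.30 (adjusted p = 0.0248), and Smc1b, a meiotic cohesin subunit, rose by 1.42 ± 0.17 (adjusted p = 0.0127).

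Further genes that rose were Ttll2 of the tubulin tyrosine ligase-like family (at least 5.46-fold), Fam227b (2.11), Mesp2 (2.02), Ocel1 (1.68), the chemokine receptor gene Ccr6 (1.496), Slc25a41 (1.49), the complement protease gene Masp2 (1.48) and the phospholipase gene Pla2g4e (1.45). The Ccr6 value is a mean over 4 probes, and its rise rests largely on probe A_55_P2108943, whose usage is given below. Further genes that fell were 4930555K05Rik (-3.11), 4933406I18Rik (-2.04), Srarp (-1.82), Eqtn (-1.78) and Gm10439 (-1.76). All 20 genes named by the rule kept their sign on each of the 3 slides that held both genotypes. The rule fixed this in advance, as it took only genes whose arrays did not overlap between the genotypes. On chromosome 4 lie 6 of the 20. Of the 20, 16 were also called with the same sign in the Slm1 knockout against wild type. Of 31863 gene values, 117 rose and 117 fell (234 in all), 47.4% of them without a symbol, and 2978 had an unadjusted p under 0.05. With slide as a block, 63 values were called (25 higher, 38 lower), 55 of them among the 234, and 15 of the 20 named genes kept their call. The 5 that did not were Ttll2, Sycp1, Ocel1, Ccr6 and Smc1b, with block adjusted p of 0.109, 0.0753, 0.0806, 0.0819 and 0.12. Probes well above background on all 9 arrays gave 4930555K05Rik and Gm10439 differences of 0.20 and 0.14, so their falls rest on dimmer probes.

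Genes of the meninges, the membranes around the brain, were shifted up in the double knockout. All 12 measured markers lay above wild type (median 0.40), led by Ogn (1.19 ± 0.56) and Islr (1.05 ± 0.48), and Ptgds lay at 0.73 ± 0.41. The list passed camera (adjusted p = 4.77e-05; 5.65e-05 with slide as a block) but not with an estimated correlation (p = 0.137, adjusted p = 0.932), and none of its members passed alone. Activity-regulated transcription factors and their kin lay higher in 19 of 20 cases (median 0.31, adjusted p = 0.000848), among them Egr2 (0.93 ± 0.42), Egr3 (0.57 ± 0.23), Junb (0.53 ± 0.22) and Fos (0.49 ± 0.26). With an estimated correlation this list did not pass (p = 0.233, adjusted p = 0.932). Oxidative phosphorylation genes were shifted slightly down, with 3 of 34 members positive (median -0.07, adjusted p = 9.73e-06) and Sdhd at -0.23 ± 0.06 and Ndufa9 at -0.22 ± 0.06; it did not pass with an estimated correlation (p = 0.189, adjusted p = 0.932). Choroid plexus and ependyma markers were lower, with 1 of 14 positive (median -0.38, adjusted p = 0.000848), such as Ccdc153 (-1.53 ± 0.48) and Rarres2 (-0.50 ± 0.14). They did not pass with an estimated correlation (p = 0.204, adjusted p = 0.932), and their medians on slides 1, 2 and 3 were -0.85, 0.01 and -0.07.

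Smaller upward shifts passed for markers of endothelium (median 0.17, adjusted p = 0.00587; Pecam1 0.34 ± 0.08) and interferon-response genes (median 0.13, adjusted p = 0.0294; Ifitm3 0.49 ± 0.15). Neither passed with an estimated correlation (p = 0.122 and 0.229, adjusted p = 0.932), and interferon response was lost with quantile normalization (adjusted p = 0.0692). Smaller downward shifts passed for astrocytes (median -0.10, adjusted p = 0.00564; Aqp4 -0.38 ± 0.08) and microglia (median -0.06, adjusted p = 0.0294; Siglech -0.38 ± 0.13). Neither passed with an estimated correlation (p = 0.0715 and 0.368, adjusted p = 0.932 and 0.989), and microglia were lost with quantile normalization (adjusted p = 0.0539). The STAR family list passed as well (adjusted p = 0.042) but not with slide as a block (0.216), quantile normalization (0.133) or an estimated correlation (p = 0.0644, adjusted p = 0.932), and holds the targeted genes themselves. Within slides 1, 2 and 3 the medians were 0.40, 0.20 and 0.67 for meninges, 0.33, 0.06 and 0.37 for activity genes, and -0.14, -0.05 and -0.03 for oxidative phosphorylation. They were 0.18, 0.08 and 0.12 for endothelium, 0.18, 0.01 and 0.19 for interferon response, -0.17, -0.06 and -0.06 for astrocytes, and -0.21, -0.04 and 0.04 for microglia. The other 23 lists had adjusted p between 0.201 and 0.997. They included markers of dopaminergic, serotonergic, cholinergic, GABAergic and glutamatergic neurons, of oligodendrocytes and their precursors, and of blood and pituitary. Markers of cerebellum, forebrain, hindbrain, and thalamus and hypothalamus were among them too. The rest were genes of splicing regulation, polyadenylation, synaptic adhesion, presynaptic release, the postsynaptic density, cholesterol synthesis, heat shock, the circadian clock, the interleukin-1 receptor family and the known splicing targets. Among the 559 list memberships, a count in which genes on several lists recur, Khdrbs1 fell and Gabra2, a subunit of the GABA-A receptor, rose. The Gabra2 rise was 0.81 ± 0.10 (limma adjusted p = 0.0127, and 0.0753 with slide as a block). Adjusted over the list alone, 1 member each passed among astrocyte (Aqp4), endothelial (Pecam1), oligodendrocyte precursor (Lhfpl3) and postsynaptic density (Gabra2) genes. Il1rap passed among the known targets, Il1r1 and Il1rap passed in the interleukin-1 receptor list, and Khdrbs1, Khdrbs2 and Khdrbs3 passed in the STAR family.

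The largest rises in probe usage in the double knockout were at Ccr6, Khdrbs1 itself, Sv2c and Pcdh15. Pcdh15 encodes a protocadherin known from the tip links of hair cells; its probe A_55_P2176160 rose in usage by 3.50 ± 0.18 (adjusted p = 0.000433; 0.033 with slide as a block), by 3.55, 3.21 and 3.73 on the 3 slides. The same probe differed by -0.23 in the Slm1 knockout (adjusted p = 0.486), and the double knockout exceeded the Slm1 knockout by 3.72 (adjusted p = 0.000453). The gene value of Pcdh15 over its 39 probes differed by 0.16. In Cp, which encodes the ferroxidase ceruloplasmin, probe A_55_P2087607 fell in usage by 2.59 ± 0.15 and probe A_56_P166278 by 2.40 ± 0.09 (adjusted p = 0.000755 and 7.58e-05), and the latter lay below the Slm1 knockout by 2.32 (log2 -2.32, adjusted p = 0.000118).

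Further usage increases were found for Ccr6 A_55_P2108943 (at least 29.4-fold), Khdrbs1 A_56_P011549 (4.31), Sv2c A_56_P237607 (4.15; SV2C is a synaptic vesicle glycoprotein) and Sycp1 A_56_P171274 (at least 1.74-fold). Others were Fhod1 A_56_P127412 (at least 4.47-fold), Zfp992 A_56_P230520 (2.32), Gm8909 A_55_P1956160 (2.31), Cd163l1 A_56_P042440 (2.28) and Draxin A_56_P011531 (at least 1.77-fold). Further decreases were found for Khdrbs1 A_56_P011547 (at least 37.1-fold), Zbtb8os A_56_P230997 (at least 18.1-fold), Plaa A_55_P2080225 (at least 10.1-fold) and Med8 A_66_P107680 (-3.73; a mediator subunit). Others were Disp3 A_55_P2097156 (adjusted p = 0.000755, not well above background on 1 double knockout array), Zfp933 A_52_P88793 (-3.05), Atg4c A_55_P1961099 (-2.70, an autophagy protease), Fam227b A_56_P027637 (-2.57) and Sycp1 A_56_P244094 (-2.48). The gene values of Fam227b and Sycp1 rose by 2.11 and 2.15, so their falls in usage follow in large part from the rise of their other probes. In all, 256 probes rose and 218 fell in usage (474 of 173120, in 296 genes; 12069 with an unadjusted p under 0.05). Of the 20 probes named by the rule, 16 were also called with the same sign in the Slm1 knockout against wild type. All 20 kept their sign on each slide, which the naming rule again fixed in advance. On chromosome 4 lie 10 of the 20, and 11 kept their call with slide as a block, which called 121 probes (82 of them among the 474). The 9 that did not were in Ccr6 (block adjusted p = 0.0736), Sv2c (0.0571), Sycp1 A_56_P171274 (0.0571), Fhod1 (0.103), Zfp992 (0.0619), Gm8909 (0.089), Cd163l1 (0.053), Draxin (0.0637) and Fam227b (0.0556).

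Il1rap, which encodes the interleukin-1 receptor accessory protein and makes membrane-bound and soluble forms through alternative 3′ ends, changed at 7 of its 15 probes in the double knockout. Probe A_52_P467232, listed under transcript NM_134103, rose in usage by 1.69 ± 0.11 (adjusted p = 0.000936; 0.0264 with slide as a block), by 1.76, 1.67 and 1.66 on the 3 slides, and its own signal rose by 2.08 ± 0.17 (adjusted p = 0.00379), a call lost with slide as a block (0.169). Probes A_56_P086629, A_56_P086630 and A_56_P086627 of the same transcript rose in usage by 0.96, 0.82 and 0.54. Probes A_56_P086634 (NM_008364), A_56_P086633 and A_56_P086632 (both NM_001159317) fell in usage by 0.86, 0.59 and 0.54; their own signals differed from wild type by -0.31, -0.05 and -0.00, so the falls in usage follow in part from the rise of the other probes. With slide as a block, A_56_P086634 kept its call (0.0461) and the other 5 did not (0.0637 to 0.135). In the Slm1 knockout, A_52_P467232 differed from wild type by -0.12 in usage (adjusted p = 0.541), and the double knockout exceeded the Slm1 knockout by 1.82 (adjusted p = 0.000718). A probe listed under one transcript may also lie in an exon shared with others.

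**Figure D2:**
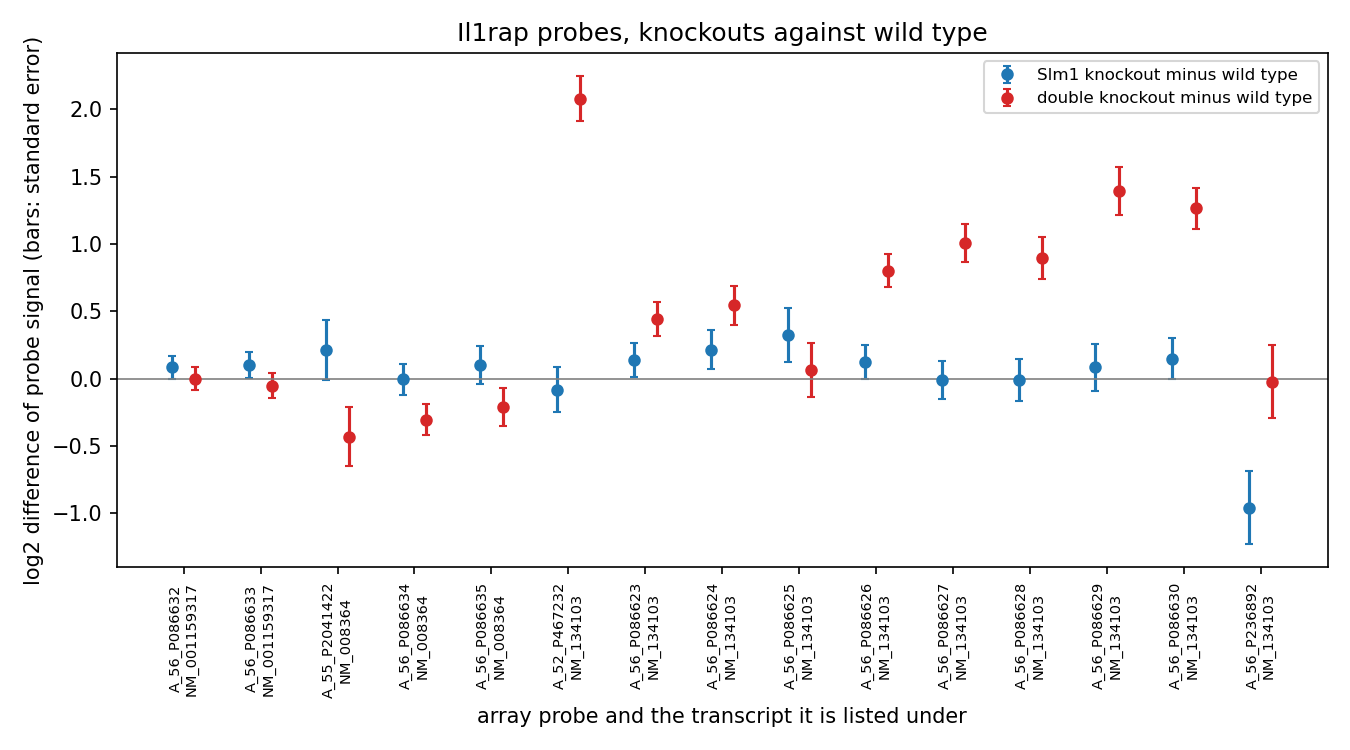
Log2 difference in signal from wild type (vertical axis) of each Il1rap probe, grouped by the transcript it is listed under (horizontal axis), for the Slm1 knockout and the double knockout; points are limma estimates and bars their standard errors over 3 arrays per genotype. Probe A_52_P467232 stands highest in the double knockout at 2.08, while in the Slm1 knockout it lies at -0.08.

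Known splicing targets of the STAR proteins were over-represented among genes with changed usage: 4 of 20 had a called probe, against 292 of 14413 other genes (odds ratio 12.1, 95% interval 2.92 to 37.7, Fisher's exact p = 0.000648). Besides Il1rap and Pcdh15 these were Kif21a, a kinesin gene, whose probes A_56_P214083, A_56_P214082 and A_56_P249137 rose in usage by 0.87, 0.60 and 0.35, and Nrxn2, a presynaptic adhesion gene, whose probe A_56_P004728 rose by 0.39 ± 0.04. With slide as a block these 4 probes had adjusted p of 0.0509, 0.0599, 0.151 and 0.0995. Over all probes tested, 12 of the 585 probes of the list were called, against 474 of 173120 in all. Adjusted over the list alone, 35 probes in 7 genes were called. The 20 list genes thus had more tested probes each than the 14433 genes in all, and so more chances of a call. Fisher's exact test on genes did not account for this. Il1rap was picked by the study on these same samples, so its place in the list and the count over the list alone are not independent evidence. Without Il1rap, 3 of 19 genes had a called probe (exact p = 0.00649), through 5 of 570 probes. Without Il1rap, Pcdh15 and Kalrn, an alternative chosen after seeing the data, 2 of 17 had (exact p = 0.0466). These 2 were Kif21a and Nrxn2, whose 4 called probes all lost their call with slide as a block. None of these shares was tested with slide as a block.

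The Slm1 knockout was compared with wild type to find what the loss of SLM1 alone changes, with the library labelled Slm1 knockout replicate 2 included. Sycp1 rose by 2.32 ± 0.30 and Ttll2 was at least 7.39-fold higher. Fam227b (2.33), Gdpd3 (2.70), the formyl peptide receptor gene Fpr2 (2.12), LOC547349 (2.09), Ocel1 (1.76), Mesp2 (1.62), H2-Bl of the class I histocompatibility genes (1.60) and Zfp987 (1.52) rose as well. Zfp982 fell by 2.86 ± 0.21 (adjusted p = 0.00119), D4Ertd617e was lower by at least 3.33 on the log2 scale. 4930555K05Rik (-2.51), Srarp (-2.39) and Eqtn (-1.96) fell too. Probes of Pou1f1 (a pituitary transcription factor), Rnf183, Olfr71 and Gm14692 were not well above background in the Slm1 knockout and lay at least 1.58-, 1.25-, 1.09- and 1.17-fold lower, while Nudt16l2 was called with no fold that its bound allows. Using only probes well above background on all 9 arrays turned Mesp2 to -0.48 and 4930555K05Rik to 0.34.

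In total 263 gene values rose and 508 fell (771 of 31863; 5460 with an unadjusted p under 0.05), 60.7% of them without a symbol. Of the 20 named genes, 7 lie on chromosome 4 and 10 were called with the same sign in the double knockout. None of the 32 lists passed camera in limma (adjusted p = 0.523 to 0.963; 1 list with an unadjusted p under 0.05, 0 with an estimated correlation), and without the library labelled Slm1 knockout replicate 2 the GABAergic neuron and interferon lists passed, both downward (adjusted p = 0.00978 for each). Of the list members, Gabra2 rose (0.92 ± 0.10) and the splicing regulator gene Srsf11 (-0.52), the oligodendrocyte gene Ermn (-0.39), Lhfpl3 (-0.38) and Pou1f1 fell. With slide as a random block 288 gene values were called, and 494 without the library labelled Slm1 knockout replicate 2. Among named genes and probes of both contrasts with the Slm1 knockout, slide as a random block lost the call of 60 and left 100 the same. Without that library, over all contrasts, 49 named results lost their call, 1 reversed and 165 stayed the same.

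Probe usage in the Slm1 knockout rose most at Trpm1 A_56_P054157 (by at least 3.17 on the log2 scale), Ccr6 A_55_P2108943 (at least 22.7-fold), Sv2c A_56_P237607 (3.35 ± 0.40), Zfp992 A_56_P230520 (2.83) and Gm8909 A_55_P1956160 (2.64). It rose also at Zfp982 A_56_P226378 (2.38), Gdpd3 A_56_P045467, Fhod1 A_56_P127412 (at least 4.68-fold), Fkbp6 A_56_P063737 (at least 3.89-fold) and Sycp1 A_56_P171274 (at least 1.63-fold). The gene value of Zfp982 fell by 2.86, and this probe fell too, by less than the gene's other probes. Usage fell at Gdpd3 A_56_P045464 (-3.20), Zfp933 A_52_P88793 (-3.04), Sycp1 A_56_P244094 (-2.69), Zbtb8os A_56_P230997 (adjusted p = 0.0118) and Med8 A_66_P107680 (adjusted p = 0.000558). The gene values of Gdpd3 and Sycp1 rose by 2.70 and 2.32, so their falls in usage follow in large part from the rise of their other probes. For probe usage, sizes are left out here and below for probes that were well above background on only some arrays of a genotype. Bounds for genes were given in such cases too, such as Pou1f1, well above background on 2 of 3 wild type arrays. Probes dim in the Slm1 knockout fell in Plaa A_55_P2080225 (at least 6.50-fold), Bpifb6 A_56_P023529 (at least 4.95-fold), Fam227b A_56_P027640 (at least 4.90-fold), Rufy4 A_56_P080692 (at least 2.67-fold) and Rbm45 A_56_P030146 (at least 1.41-fold). Kalrn changed at 7 probes, with A_56_P085293 falling by 0.99 ± 0.05 (adjusted p = 0.0005) and then differing by 0.89 in the double knockout against the Slm1 knockout (adjusted p = 0.00067). Further known targets with a called probe were Pcdh15, Mtor, Cadm1, Dgkb, Clasp2, Cask, Sgce and Kif21a. That made 9 of 20 known targets, against 4713 of 14413 other genes (odds ratio 1.68, 95% interval 0.616 to 4.47, exact p = 0.242), with 19 probes called over all probes and 15 adjusted over the list alone. In all 7713 of 173120 probes were called in 4722 genes (2887 higher, 4826 lower), and 3037 with slide as a random block.

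The double knockout was compared with the Slm1 knockout to find what the further loss of SAM68 changes. Khdrbs1 fell by 1.68 ± 0.06 (adjusted p = 0.000116) and the amylase genes Amy2a5, Amy1 and Amy2b fell by 2.40, 2.26 and 1.53. Also lower in the double knockout were 4933406I18Rik (-1.94), the chitinase gene Chia1 (-1.90), 1700001J03Rik (-1.75), 4930449I24Rik (-1.63), Spink10 (-1.55) and Vmn2r-ps11 (-1.30, but 0.30 over probes well above background on all 9 arrays). Ch25h, which encodes cholesterol 25-hydroxylase, rose by 1.94 ± 0.40 (adjusted p = 0.0441). The genes Olfr71, Olfr27, Rnf183, Pou1f1, Gm14692, Gm10578 and Gm40787 were not well above background in the Slm1 knockout and lay at least 1.12-, 1.42-, 1.05-, 1.44-, 1.05-, 1.12- and 1.09-fold higher in the double knockout, while AI662270 and Nudt16l2 have no fold that their bounds allow.

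In this contrast 791 gene values rose and 279 fell (1070 of 31863; 6588 with an unadjusted p under 0.05). Scaling by quantile normalization gave 554 and 346. Meningeal markers were shifted up, 12 of 12 positive (median 0.66, camera adjusted p = 0.000413, with Ogn at 1.97 ± 0.56). Interferon-response genes were too (17 of 20 positive, median 0.18, camera adjusted p = 0.0055, Irf9 up by 0.31 and Oasl2 by 0.54). So were activity genes (19 of 20 positive, median 0.29, camera adjusted p = 0.00759, Fosl2 up by 0.63 and Arc by 0.44). These shifts rest on the same double knockout arrays as those against wild type, so they are not a repeat of them. In the Slm1 knockout, 1 of 12 meningeal markers lay above wild type (median -0.17), so part of the meningeal shift lies there. None of the 3 passed with an estimated correlation (adjusted p = 0.945 with an estimated correlation), and the other 29 lists had adjusted p of 0.0648 to 0.922. Adjusted over the list alone, 8 meningeal, 6 interferon-response and 2 activity genes passed. Other list members that passed over all genes were Il1r1 (0.77), Il1r2 (-0.38), Srsf11 (0.55), the polyadenylation factor gene Pcf11 (-0.28), Ndufa9 (-0.38), Ermn (0.63), Rarres2 (-0.77) and Pou1f1. Without the library labelled Slm1 knockout replicate 2, 586 gene values and 5 lists were called.

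Probe usage rose at Khdrbs1 A_56_P011549 (4.51), Pcdh15 A_55_P2176160 (3.72) and Adam5 A_56_P240549 (adjusted p = 0.00606), and at probes not well above background in the Slm1 knockout in Bpifb6 (A_56_P023529, at least 4.67-fold), Fam217a (A_56_P226869, 3.63), Rufy4 (A_56_P080692, 2.23), Ash2l (A_56_P130786, 1.49), Ticrr (A_56_P039936, 1.43), Msr1 (A_56_P240743, 1.40) and Slc22a2 (A_56_P106448, 1.37). It fell at Khdrbs1 A_56_P011547 (at least 43.9-fold), Cp A_56_P166278 (-2.32), Lrrcc1 A_55_P2064917 (-1.76), Nynrin A_56_P245885 (at least 2.70-fold) and Ttc21a A_56_P143352 (at least 1.84-fold). It fell also at 1700093K21Rik A_56_P197088, Fanci A_56_P233144, Heg1 A_56_P236873, Cd247 A_56_P235614 and Cyp3a57 A_56_P059345 (adjusted p = 0.0276, 0.0234, 0.0208, 0.0491 and 0.00689). In all 10282 probes were called in 5827 genes (5968 higher, 4314 lower), 3983 of them with slide as a random block. Known targets had a called probe in 12 of 20 genes against 5815 of 14413 (odds ratio 2.22, 95% interval 0.833 to 6.26, exact p = 0.108), with 42 probes called over all probes and 47 adjusted over the list alone.

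Sycp1, Fam227b, Zfp982 and D4Ertd617e by gene value and Med8 by probe usage moved the same way in both knockouts. Of the 234 gene values called in the double knockout, 133 were called with the same sign in the Slm1 knockout and 1 with the opposite sign; independent lists would share 2.83 and unchanged groups against the same controls shared 0.1 on average in 20 simulated draws (at most 1). For probe usage, 298 probes were shared with the same sign and 7 with the opposite sign, against 10.3 for independent lists and 0 in the simulated draws. The draws held no changed gene or probe, so shared counts near 0 were set in advance. They cannot show how much overlap the shared controls add to lists as long as the real ones. Across gene values the differences of both knockouts from wild type correlated at r = 0.382 (0.498 in the draws), with a covariance of 0.0297 against 0.0190 from the shared controls, a difference of 0.0107. For probe usage that difference was 0.00197. Genes are not independent replicates, the 3 wild type arrays were too few to split, and part of the excess may come from the shared controls.

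Chromosome 4, which carries Khdrbs1, held many of the genes called against wild type, among them Zfp982, Zfp985, D4Ertd617e, Srarp, Eqtn and Masp2 by gene value and Med8, Plaa, Zbtb8os, Atg4c and Disp3 by probe usage. In the double knockout 39 of 1241 genes on this chromosome were called, against 83 of 18738 elsewhere (odds ratio 7.29, 95% interval 4.83 to 10.8, Fisher's exact p = 3.92e-18). In the Slm1 knockout, in which Khdrbs1 is intact, 61 of 1241 were called against 242 of 18738 (odds ratio 3.95, exact p = 1.92e-16). For the double knockout against the Slm1 knockout the value given here covers another region, the 10 Mb around each targeted gene. Genes there had an odds ratio of 0.802 (95% interval 0.342 to 1.61, exact p = 0.743), which is not a value for chromosome 4. Within 10 Mb of Khdrbs1, 13 of 316 genes were called in the double knockout (odds ratio 7.70), and within 10 Mb of Khdrbs2, on chromosome 1, 1 of 101 (odds ratio 1.63, 95% interval 0.0406 to 9.48). By probe usage, 3 of 71 genes within 10 Mb of Khdrbs2 had a call in the double knockout (odds ratio 2.15, exact p = 0.174) and 7 of 130 within 20 Mb (odds ratio 2.80, 95% interval 1.09 to 6.02, exact p = 0.0166), and against the Slm1 knockout 69 of 130 had one within 20 Mb (odds ratio 1.66, exact p = 0.00401). For probe usage, 82 of 889 genes on chromosome 4 had a call in the double knockout against 202 of 13141 elsewhere (odds ratio 6.51, exact p = 6.75e-33); without chromosome 4, an alternative chosen after seeing the data, 250 usage calls were left. Chromosome 17, which carries Ttll2, Fpr2, LOC547349 and H2-Bl, held 27 called genes of 985 in the Slm1 knockout (odds ratio 1.91, adjusted p = 0.0293) and 12 of 985 in the double knockout (odds ratio 2.12, exact p = 0.0194, adjusted p = 0.129).

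**Figure D3:**
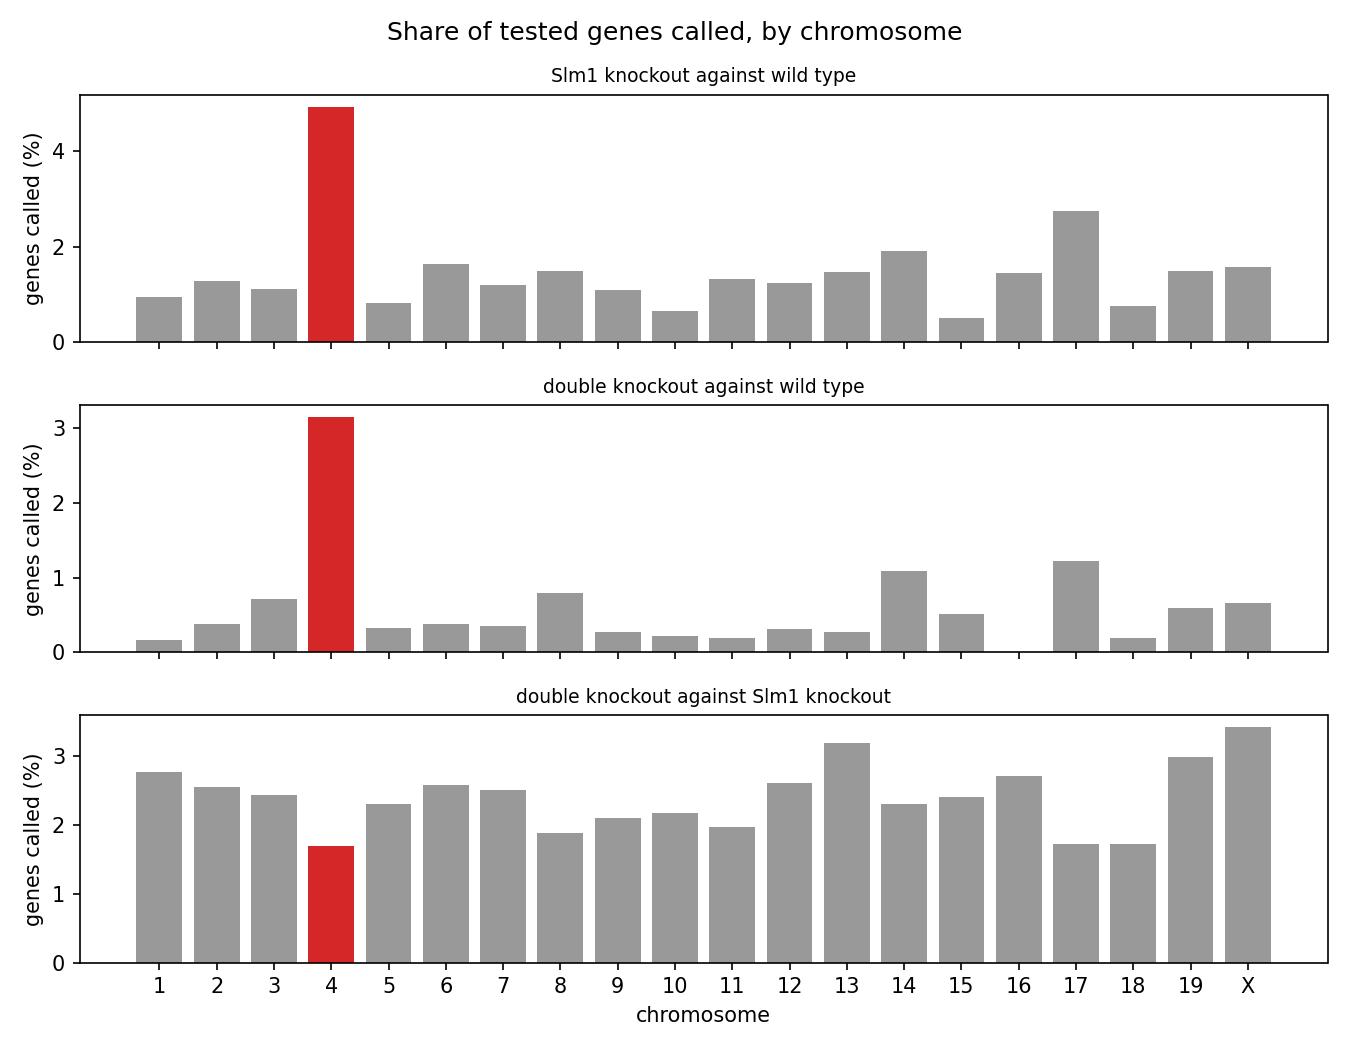
Share of tested genes called by gene value (vertical axis, percent) on each chromosome (horizontal axis) in the 3 contrasts, with chromosome 4 in colour; each panel has its own scale from 0. Chromosome 4 stands highest against wild type, at 4.92% of genes in the Slm1 knockout and 3.14% in the double knockout, but not between the double knockout and the Slm1 knockout.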

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

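The fits with slide as a random block over all 9 arrays, those without chromosome 4 and the lists without the library labelled Slm1 knockout replicate 2 were chosen after seeing the data. Of counts and tests, 114 kept their size, 75 became weaker and 19 stronger, and of single genes and probes 3794 kept sign and call, 885 lost the call, 2 gained it and 16 reversed. The cause was not tested unless stated.

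Background correction with normexp called 1500 gene values in the Slm1 knockout against wild type and 1579 for any difference among the 3 genotypes. Array weights called 1955, 749, 1894 and 2491 gene values and 19824, 2063, 21855 and 21305 probes, in the order Slm1 knockout against wild type, double knockout against wild type, double knockout against Slm1 knockout, and any difference. For the double knockout against wild type, diffSplice called 1260 probes, and slide as a random block over all 9 arrays 879 gene values and 2700 probes. Slide as a random block called 288 and 325 gene values and 3037 and 3983 probes in the 2 contrasts with the Slm1 knockout, and 5194 probes for any difference. Fits to only the 6 arrays compared, with fewer degrees of freedom, called 235 gene values and 2258 probes in the Slm1 knockout against wild type and 198 and 1960 in the double knockout against the Slm1 knockout. Without chromosome 4, where fewer genes were tested, 250 probes were called in the double knockout against wild type.

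With the replicate block 488 gene values were called in the Slm1 knockout against wild type, 124 in the double knockout against wild type, 680 in the double knockout against the Slm1 knockout and 606 for any difference. With the slide block, 63 gene values and 121 probes were called in the double knockout against wild type, and 24 of the single results lost their call.

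Lists past the test fell from 9 to 0 in the double knockout against wild type and from 3 to 0 in the double knockout against the Slm1 knockout with an estimated correlation, and from 9 to 6 with quantile normalization. Without the library labelled Slm1 knockout replicate 2 they numbered 2 in the Slm1 knockout against wild type and 5 in the double knockout against the Slm1 knockout. Khdrbs2 probe A_56_P076294 was then called in the double and Slm1 knockout (adjusted p = 0.000442 and 0.000228); the fitted -5.40 and -5.13 are not sizes, as no knockout array left was well above background.

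Leaving out each library in turn, with fewer arrays in the fit, gave 196 to 1076 gene values in the Slm1 knockout against wild type, 63 to 290 in the double knockout against wild type, 259 to 1908 in the double knockout against the Slm1 knockout and 372 to 1463 for any difference. The ranges for probe usage were 1735 to 7080, 162 to 756, 2371 to 8705 and 2811 to 6423. Gene counts in the same order moved by over 1.5 times without wild type replicate 1 (242, 88, 643 and 462), replicate 2 (212, 80, 513 and 378) and replicate 3 (196, 63, 543 and 372), and without double knockout replicate 2 (494, 112, 279 and 474) and replicate 3 (478, 84, 259 and 422). The last 3 of these moved without double knockout replicate 1 (141, 325 and 574). All but the second moved without Slm1 knockout replicate 1 (369, 393 and 466) and the library labelled Slm1 knockout replicate 2 (494, 586 and 645), and the third rose to 1908 without Slm1 knockout replicate 3. Probe counts moved without wild type replicate 1 (2095, 211 and, for any difference, 4088), replicate 2 (1735, 168, 5040 and 2811) and replicate 3 (1951, 162, 5588 and 3096), and without double knockout replicate 2 (4201, 226, 2371 and 3108) and replicate 3 (4615, 204, 3018 and 3527). They also moved without double knockout replicate 1 (232, 2894 and 4602), Slm1 knockout replicate 1 (3628, 4363 and 3081) and the library labelled Slm1 knockout replicate 2 (4735, 5706 and 4026), and the double knockout against wild type rose to 756 probes without Slm1 knockout replicate 3.

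The uncalled Khdrbs2 gene value reversed most. With normexp it became 0.0017 for the double knockout against wild type and 0.0365 against the Slm1 knockout. Over probes well above background on all 9 arrays, which leave out A_56_P076294, it became 0.199, 0.118 and, for the Slm1 knockout against wild type, 0.0807. The median over probes gave 0.465, 0.414 and 0.0508. Leaving out each library moved the double knockout against the Slm1 knockout from -0.207 to 0.0836, with 0.0836 without the library labelled Slm1 knockout replicate 2 and 0.0181 without double knockout replicate 3. Over probes well above background on all 9 arrays, which are fewer, Mesp2 became -0.48 and 4930555K05Rik 0.34 in the Slm1 knockout, 4930555K05Rik 0.20 and Gm10439 0.14 in the double knockout, and Vmn2r-ps11 0.30 in the double knockout against the Slm1 knockout. The Khdrbs3 difference of the latter contrast became -0.0013 with the median over probes, and that of the double knockout against wild type was called with array weights (0.40, adjusted p = 0.0459) and with slide as a random block over all 9 arrays (0.41, adjusted p = 0.0377). Signal over background set limits: 15.8% of probes in the Slm1 knockout and 12.8% in wild type were not well above background on any array, and 11.3% of genes called in the Slm1 knockout against wild type were dim in the Slm1 knockout, against 1.43% of genes tested. The last exon share was not run.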

Other observations

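A few synaptic genes changed in probe usage in the double knockout and were picked out after the values were seen; no enrichment was tested. Calls were found in 2 of 38 postsynaptic density, 3 of 28 presynaptic release and 2 of 28 synaptic adhesion genes, against 296 of 14433 genes in all. Dlgap1, which encodes a scaffold protein of the postsynaptic density, rose at probe A_56_P100695 by 0.97 ± 0.06 (adjusted p = 0.000689; 0.0426 with slide as a block) and at A_55_P1959728 by 0.53 ± 0.04 (adjusted p = 0.00324; 0.0713 with slide as a block). Probe A_56_P100695 differed by -0.18 in the Slm1 knockout (adjusted p = 0.115) and by 1.15 between the double knockout and the Slm1 knockout (adjusted p = 0.000453). Rims2, which encodes a protein of the presynaptic active zone, rose at A_56_P218053, A_56_P218052 and A_56_P218054 by 0.63, 0.58 and 0.53, with block adjusted p of 0.0904, 0.0889 and 0.145. Its relative Rims1 fell by 0.39 at A_56_P079167, and Lrrtm4, a synaptic adhesion gene, rose by 0.42 at A_56_P159835.

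Calls over other splits of the arrays were counted as planned. For gene values, the split by genotype gave 771, 234 and 1070 calls in the Slm1 knockout against wild type, the double knockout against wild type and the double knockout against the Slm1 knockout, and the highest of the other splits gave 0, 0 and 2. For probe usage the counts were 7713, 474 and 10282 against 0, 0 and 2. In each contrast 1 split of 10, the real one, reached the real count, and 10 splits are too few for a share under 0.05. For any difference among the 3 genotypes, 1 of 100 splits, the real one, reached 1015 gene values and 8438 probes; the highest others gave 266 and 5757, in splits that kept the 3 Slm1 knockout arrays together, and 93 and 181 among those that did not.

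Genes called in both knockouts clustered on chromosome 4, and 3 explanations were weighed; the last 2 tests were chosen after the result was seen. The first was donor sequence of strain SV129 beside the targeted genes. In the double knockout, genes within 10 Mb of either gene were called with an odds ratio of 6.26 (95% interval 3.28 to 11.1), 13 of the 14 near Khdrbs1. In the Slm1 knockout, however, 18 of 316 genes near the intact Khdrbs1 were called, so the odds ratio does not tie these calls to its targeting. Near the targeted Khdrbs2, 0 of 101 genes were called in the Slm1 knockout. The 95% interval of that odds ratio reached 2.42 (Fisher's exact p = 0.411), too wide to decide on sequence beside Khdrbs2. For most usage calls on chromosome 4, the values argue against donor sequence that came only with the disrupted Khdrbs1 allele. At called chromosome 4 probes the Slm1 knockout stood at a median of 0.957 of the way from wild type to double knockout (interquartile range 0.769 to 1.096, n = 146 probes). Elsewhere the median was 0.476 for 303 probes. The test took probes from the whole chromosome, several of which can belong to the same gene. It does not decide on the stretch beside Khdrbs1 or on the probes with lower positions. Strain mismatches under the probes stayed open, with 58.2% of the 146 chromosome 4 probes lower in the double knockout (95% interval 49.8 to 66.3), against 40.6% elsewhere.

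The signal of Khdrbs2 probe A_56_P076294 in the library labelled Slm1 knockout replicate 2 had 4 possible explanations, and the test of a wild type animal was chosen after the result was seen. A spot artefact was excluded, since its 2 spots lay within 1.15-fold (47.8 and 55.1). A wild type animal of another line stayed open: the value stood at -7.78 wild type SDs from the wild type mean, but this sets 1 array of one scan against 3 of another and decides nothing. Both admixed RNA of the wild type mice measured here and an animal of theirs were excluded by the median position of 1.04 between wild type (0) and double knockout (1) at 77 chromosome 4 probes (interquartile range 0.960 to 1.31); the position had been seen as 1.05 on the usage scale (81 probes) before it was computed on signal as written. Possibly the animal carried 1 intact copy of Khdrbs2, which stayed open as well because 0 probes qualified for the test.

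Contrasts with the Slm1 knockout arrays may reflect their separate scan: of the genes called against wild type, 53.8% were called with the same sign against the double knockout (415 of 771), and 64.2% of probes were (4953 of 7713). Scan and loss of SLM1 with SAM68 present would both give this pattern and cannot be told apart. Both contrasts also share the Slm1 knockout arrays, which by itself favours the same sign, and the share without any change was not computed.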
